A study of Homo sapiens with 4 samples.

How the data were processed

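Poly(A) RNA of HEK293T cells was sequenced in 4 libraries, 2 labelled DIMT1_WT and 2 labelled DIMT1_E85A. HEK293T is an established human embryonic kidney line that carries the SV40 large T antigen. Per the labels, the cells carried a heterozygous DIMT1 knockout and overexpressed either wild-type DIMT1 or the E85A variant, although the genotype field of the DIMT1_WT libraries reads only "wild type". Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected on beads, ribosomal RNA was further depleted, the RNA was fragmented by sonication and libraries were made with a strand-specific mRNA kit. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between the libraries of the authors' fit, which may be technical.

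Per the submitters' processing notes, the authors used the hg38 build, HISAT2 and DESeq2, with no versions. The read counter, its annotation and its strand setting are not given in the sources used here. The measurements were taken from the authors' deposited table of 1 comparison, which lists 26485 gene symbols. For each gene the authors deposited a mean normalized count (a signal scaled by library size), a log2 fold change with its standard error, a Wald statistic (a score), and a p-value with an adjusted p-value. The deposited header does not state the direction of the log2 fold change, which was taken from the table's name as DIMT1_E85A against DIMT1_WT.

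The deposited columns were checked against each other. The score equalled the log2 fold change over its error, the p-value was a normal two-sided one, and the adjusted p equalled a Benjamini-Hochberg adjustment over 13280 genes. These 13280 tested genes had a deposited mean of at least 13.3. A further 6263 genes had a mean of 0, and 6942 had a score without an adjusted p. The lowest deposited means fell on 8 distinct steps, each the value of 1 read in 1 library. All 2417 means under 0.5 (100%) were whole-number sums of these steps within 1e-07, against 0% of random values. The steps had been found among the lowest of these means, which are sums by construction, so only the higher of them test the steps. The fit behind the deposited table therefore held 8 libraries, of which 4 lay outside the 2 compared groups, and the deposited standard errors and p-values come from that fit. The mean normalized count is an average over these libraries, and no mean per group was derived. The steps implied size factors from 0.611 to 1.43, and both ends of this range belonged to libraries outside the 2 compared groups. Size factors were 1.25 and 0.757 where a single read gave a positive log2 fold change (DIMT1_E85A). They were 1.09 and 1.09 where it gave a negative one (DIMT1_WT). Total counts per library are unknown, so precision was read from the deposited standard errors. Their median was 0.458 at means from 13 to 100, 0.156 from 100 to 1000, and 0.0876 from 1000 upward.

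Genes were called changed at the authors' adjusted p under 0.05, and no p-value per gene was added to theirs. The share of changed genes that were higher was given an exact Clopper-Pearson 95% interval, which covers counting error only. Of 47 gene lists fixed before the data were examined, 43 with at least 5 measured members were tested on the deposited Wald statistic with cameraPR of limma 3.58.1 in R 4.3.3. The inter-gene correlation was preset at 0.01, and p was adjusted by Benjamini-Hochberg over the lists. The correlation could not be estimated from 1 value per gene. Older symbols were matched to current ones through gene name tables. This matching was settled after the list tests had first been seen, and 14 lists passed with symbols as listed, all 14 of them shared with the reported tests.

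Transcript length and GC content came from GENCODE 29 on GRCh38, as averages over the basic transcripts, for 13007 of the 13280 tested genes (97.9%). The annotation is not known to be the authors' own. The trend of log2 fold change over both properties was fitted with natural splines of 5 degrees of freedom each and subtracted. This alternative was chosen after the data were examined. In simulated log2 fold changes with the deposited errors over 13007 genes, 45% of genes changed by 0.5 and 74% of genes changed by 1 were recovered, and 0.0861% of unchanged genes were called. With a GC trend added to the simulated comparison, 23.8% of unchanged genes were called, and 0.0626% after its subtraction. The simulation changed a small share of genes and drew each gene independently with its deposited error. In the deposited comparison 40.1% of genes passed, and the Wald statistics were spread 2.65 times as widely as a standard normal, or 2.06 times after subtraction. The simulated rates of false calls therefore hold only if the deposited errors are right. With 1 list shifted in the same simulated comparison over 13007 genes, 2 lists were called, 3 with the GC trend added and 2 after its subtraction. The list called besides the shifted one, that of heat shock genes, held 2 of the single genes that had been changed at random, so a list can be called from a few strongly changed members.

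Genes were named by a rule fixed before the data were examined. It took DIMT1, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50, leaving out pseudogenes and unnamed loci. It also took the 4 members of each list with the smallest p, preset ribosome-assembly and stress genes, and the 4 genes with the highest mean. A few genes that the rule takes are not reported here, and none was put in their place. Alternatives changed the threshold, the size of change, the filter on the mean, the multiple-testing adjustment, the null distribution, the centring, the inter-gene correlation and the statistic of the list tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps. No column of the deposited table was left out.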

Results

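The transcriptomes of HEK293T cells overexpressing wild-type DIMT1 or its E85A variant on a heterozygous DIMT1 knockout background were compared by RNA sequencing. DIMT1 is the methyltransferase that dimethylates a pair of adjacent adenosines near the 3′ end of 18S rRNA. There were 2 libraries in each of 2 groups, DIMT1_E85A and DIMT1_WT. The values are those of the authors' deposited table, which gives 1 log2 fold change per gene with its standard error and no value per library, so the spread between replicates enters only through that error. Genes are positioned on GRCh38 by GENCODE 29.

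The question was which transcripts differed between cells carrying the E85A variant and cells carrying the wild-type enzyme. DIMT1 itself, a protein-coding gene on the minus strand of chromosome 5 from 62387254 to 62403939, was 2.00-fold higher in DIMT1_E85A in the authors' deposited table (log2 fold change 1.00, standard error 0.0619, adjusted p = 7.42e-56). With a mean normalized count of 12106 it stood at rank 167 of the 13280 tested genes in the authors' deposited table. The table does not separate reads of the transgene from those of the endogenous allele, and the groups therefore differed in the amount of DIMT1 mRNA as well as in the variant. In the authors' deposited table, 5328 of 13280 tested genes (40.1%) had an adjusted p under 0.05, of which 2794 were higher and 2534 lower in DIMT1_E85A. The higher genes made up 52.4% of the changed genes (95% Clopper-Pearson interval 51.1% to 53.8%). This direction depended on the centring: with values centred on the median of genes with a mean of at least 100, 2603 were higher and 2724 lower (48.9% higher, 47.5% to 50.2%), and with the trends of GC content and length subtracted 2230 were higher and 1384 lower (61.7% higher). Most changes were small: 3191 of the changed genes (59.9%) had a log2 fold change under 0.58 in size in the authors' deposited table, and 313 reached 1, 162 of them higher and 151 lower.

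The largest rises by the fixed rule were those of ribosomal RNA. In the authors' deposited table RNA18S5 had a log2 fold change of 3.44 with a standard error of 0.794, and RNA28S5 one of 2.55 with a standard error of 0.644. The error of RNA18S5 was 5.38 times the usual error of genes with a like mean in the authors' deposited table. Both are multicopy genes and both had been targets of depletion during library preparation. Among protein-coding genes, EGR1, an immediate early transcription factor, rose by 1.67 (standard error 0.341), EMP3 by 1.60 (0.130) and TIMP1, a secreted inhibitor of matrix metalloproteinases, by 1.60 (0.0824) in the authors' deposited table. The Groucho-family corepressor TLE2 (1.57), the G protein subunit GNG5 (1.49), the complex I subunit NDUFC2 (1.49), the tubulin TUBB4A (1.45), C1orf233 (1.81) and the long noncoding RNA OLMALINC (1.84) were also among the largest rises in the authors' deposited table. NDUFC2 shares exon bases with a read-through transcript on the same strand, and 4 pseudogenes are named after GNG5, so their values are uncertain where reads could be split.

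TRMT10A, a tRNA guanosine methyltransferase on chromosome 4 from 99546709 to 99564032, showed the largest fall, by 3.18 on the log2 scale in the authors' deposited table (standard error 0.942, adjusted p = 0.00287). That error was 9.04 times the usual error of genes with a like mean in the authors' deposited table. The small nucleolar RNAs SNORD22 (-1.82), SNORD76 (-1.61), SNORA18 (-1.59) and SNORD27 (-1.55) were also among the largest falls in the authors' deposited table, as was the microRNA host transcript MIR22HG (-1.81). After subtraction of the GC content and length trends SNORD22 stood at -1.25 and SNORA18 at -0.85 (adjusted p = 0.0483), and SNORD27 stood at -0.34 and no longer passed (adjusted p = 0.61). Transcript lengths from 65 to 237 bases were held by 74 small nucleolar RNAs and 15 other tested genes, so the length trend there rested largely on these RNAs. Protein-coding genes with the largest falls in the authors' deposited table were the phospholipid-binding protein gene ANXA1 (-1.74), the prefoldin subunit gene PFDN4 (-1.52), EAF2 (-1.50), CCDC181 (-1.49), ZNF567 (-1.44) and LARP7 (-1.41). LARP7 binds the 7SK RNA, and RN7SK itself, a list member, rose by 1.31 (standard error 0.125) in the authors' deposited table. Of pseudogenes, 293 are named after RN7SK and 4 after LARP7, so both values are uncertain where reads could be split. RN7SK also has no poly(A) tail, although poly(A) RNA was selected.

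**Figure D1:**
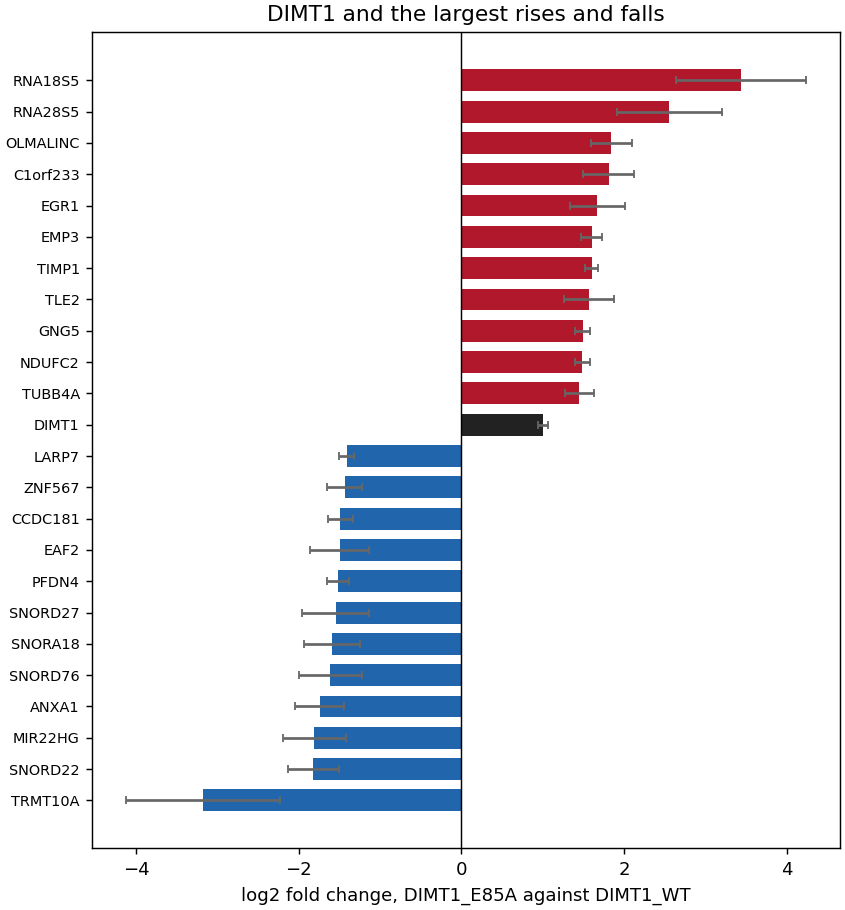
Log2 fold change of DIMT1 (black), 11 of the largest rises (red) and the 12 largest falls (blue) by the fixed rule, DIMT1_E85A against DIMT1_WT, from the authors' deposited table, with bars for the deposited standard error. Values run from -3.18 for TRMT10A to 3.44 for RNA18S5, and the errors of these 2 genes are the widest.

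Log2 fold changes followed the GC content of the transcripts. Across 13007 tested genes, which are not independent replicates, Spearman's rho between GC content and log2 fold change was 0.565, against -0.10 for transcript length and 0.0713 for the mean normalized count. Of genes with under 40% GC, 4.63% were higher and 50.1% lower in the authors' deposited table, whereas of genes with 60% GC or more 35.9% were higher and 1.53% lower. GC content accounted for 30.0% of the variance of log2 fold change, and GC content with length for 32.1%. For each of the 14 lists past the threshold, the median after subtraction of both trends is therefore given beside the median of the authors' deposited table. Of 185 named genes past the threshold with known GC content, 73 had a log2 fold change over 1.5 times smaller after subtraction than in the authors' deposited table, and 4 one over 1.5 times larger.

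**Figure D2:**
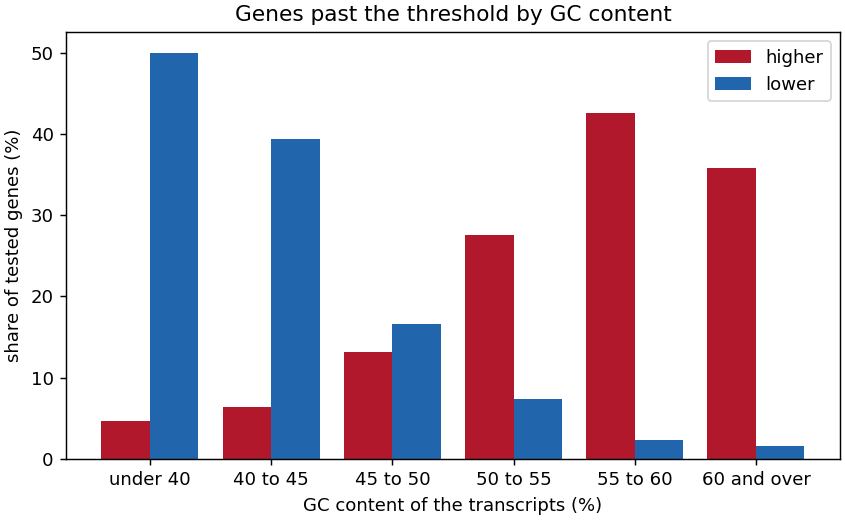
Share of tested genes (percent, vertical axis) past an adjusted p of 0.05 and higher (red) or lower (blue) in DIMT1_E85A, by GC content of the transcripts (percent, horizontal axis). The lower share goes from 50.1% in the bin with the least GC to 1.53% in the bin with the most.

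Genes for the proteins of the ribosome were mostly higher in DIMT1_E85A. Of 32 measured small-subunit protein genes 25 rose and 3 fell in the authors' deposited table (25 and 3 adjusted over the list alone), with a median of 0.49, or 0.26 after subtraction of the trends (adjusted p = 3.31e-12, and 1.38e-13 after subtraction). RPS13 (0.92, standard error 0.0662), RPS16 (0.87, 0.0562) and RPS14 (0.73, 0.0562) rose in the authors' deposited table, and RPS24 fell by 0.74 (0.0603). Of 47 large-subunit protein genes 29 rose and 10 fell in the authors' deposited table (29 and 10 adjusted over the list alone), with a median of 0.37, or 0.31 after subtraction (adjusted p = 7.2e-07 and 3.57e-09). RPLP2 (1.21), RPL8 (0.97) and RPL7A (0.94) rose in the authors' deposited table, whereas RPL34 fell by 0.81. Ribosomal protein genes have many processed copies, 37 of them named after RPL7A and 16 after RPL34, and how reads were divided among copies is not given in the sources used here. The large-subunit list had a median at percentile 95.9 of random lists of like mean, and its call was lost by that comparison. The small-subunit call held against random lists (adjusted p = 0.0226). With log2 fold changes in place of the statistic the list tests gave adjusted p of 0.00122 for the small-subunit and 0.00339 for the large-subunit list. Wald statistics were spread less widely after subtraction (2.06 against 2.65), so a smaller p after it is no sign of a larger change.

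Transcripts of glycolytic enzymes were mostly higher in DIMT1_E85A. Of 22 measured genes 15 rose and 2 fell in the authors' deposited table (16 and 2 adjusted over the list alone), with a median of 0.56, or 0.41 after subtraction of the trends (adjusted p = 2.65e-09 and 3.57e-09). ENO1, the tested gene with the highest mean, rose by 1.04 (standard error 0.0529), GAPDH by 1.03 (0.0526), GPI by 0.88 (0.0572) and PKM by 0.72 (0.0528) in the authors' deposited table. As many as 62 pseudogenes are named after GAPDH, so its value is uncertain where reads could be split. The glycolysis list had an adjusted p of 0.00041 with log2 fold changes in place of the statistic, and 0.00645 against random lists of like mean. Of 77 nuclear genes for oxidative phosphorylation 38 rose and 14 fell in the authors' deposited table (40 and 14 adjusted over the list alone), with a median of 0.23, or 0.26 after subtraction (adjusted p = 5.31e-07 and 1.27e-09). NDUFC2, NDUFB10 (1.11), the ATP synthase gene ATP5G2 (1.06) and UQCRC1 (0.84) led this list in the authors' deposited table. The oxidative phosphorylation call was lost against random lists of like mean. The sterol synthesis list had 12 genes higher and 2 lower of 24 in the authors' deposited table (12 and 3 adjusted over the list alone), with a median of 0.40, or 0.31 after subtraction (adjusted p = 0.00034 and 3.17e-06). Its members DHCR7 (0.98), FDPS (0.58) and SREBF2 (0.70), the last a transcription factor of the pathway, rose in the authors' deposited table.

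Further lists passed more narrowly in the upward direction. Autophagy and lysosome genes were higher in 25 and lower in 6 of 44 cases in the authors' deposited table (26 and 6 adjusted over the list alone), led by ATP6V0D1 (1.06), TPP1 (1.00), LAMP1 (0.89) and SQSTM1 (0.55), with a median of 0.27, or 0.22 after subtraction (adjusted p = 0.00269 and 0.00114). Of 43 spliceosome and SR protein genes 22 rose and 8 fell in the authors' deposited table (22 and 10 adjusted over the list alone), with SNRPA (0.98), SF3A1 (0.86), SF3B4 (0.85) and SNRNP70 (0.76) higher. The spliceosome median was 0.22, or 0.15 after subtraction (adjusted p = 0.00684 and 0.00036). Extracellular matrix and adhesion genes had 15 members higher and 1 lower of 45 in the authors' deposited table (14 and 1 adjusted over the list alone), among them TIMP1, FBLN1 (1.05), VIM (0.77) and NID1 (0.61). Their median was 0.30, or 0.17 after subtraction, and the call ended with subtraction (adjusted p = 0.0139 and 0.0993). NRF2 targets had 7 members higher and 3 lower of 19 in the authors' deposited table (7 and 3 adjusted over the list alone), with TKT (0.89), FTH1 (0.78), FTL (0.74) and PGD (0.62) higher and a median of 0.04, or 0.16 after subtraction (adjusted p = 0.0371 and 0.0478). The NRF2 median lay at percentile 41.3 of random lists of like mean, below their middle, against the upward direction of the list test. With an inter-gene correlation of 0.05 these 4 lists no longer passed (adjusted p from 0.0907 to 0.174).

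Zinc finger genes of the KRAB family, which encode transcriptional repressors, were lower. Of 74 measured members 41 fell and 2 rose in the authors' deposited table (43 and 2 adjusted over the list alone), with a median of -0.58, or -0.31 after subtraction of the trends (adjusted p = 1.05e-05 and 6.75e-05). ZNF33B (-0.94, standard error 0.142), ZNF184 (-0.89, 0.161), ZNF23 (-0.88, 0.155) and ZNF33A (-0.76, 0.132) fell in the authors' deposited table. The fixed list of small nucleolar RNA host genes had 14 members lower and 2 higher of 24 in the authors' deposited table (15 and 2 adjusted over the list alone), with a median of -0.44, or -0.48 after subtraction (adjusted p = 0.000161 and 1.4e-06). SNHG12 (-1.13), GAS5 (-0.90) and SNHG1 (-0.75) fell in the authors' deposited table, whereas DANCR rose by 0.69. Host genes in general did not share this direction: of the 43 tested genes that enclose the measured small nucleolar RNAs, 16 rose and 15 fell in the authors' deposited table, with a median of 0.047. The 11 of them in the fixed list had a median of -0.63 and the other 32 one of 0.20 in the authors' deposited table. Of 50 factors of 60S assembly 22 fell and 12 rose in the authors' deposited table (22 and 13 adjusted over the list alone), with a median of -0.12 before and after subtraction (adjusted p = 0.000368 and 9.45e-05). The nucleolar GTPase gene GNL3 (-1.19), RSL24D1 (-1.01), NOC3L (-0.98) and RSL1D1 (-0.83) fell in the authors' deposited table. The 60S assembly call was lost with ranks or log2 fold changes in place of the statistic and against random lists of like mean.

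Genes of G2/M and mitosis moved both ways. Of 50 members 26 fell and 10 rose in the authors' deposited table (26 and 11 adjusted over the list alone), HMMR (-0.96) and DLGAP5 (-0.80) among the falls and PLK1 (0.84) and CDC20 (0.69) among the rises. The median was -0.32, or -0.11 after subtraction, and the call ended with subtraction (adjusted p = 0.00034 and 0.133). Of 28 heat shock and chaperone genes 11 fell and 10 rose in the authors' deposited table (12 and 10 adjusted over the list alone), with HSP90AA1 (-1.13), DNAJA1 (-0.68) and CCT8 (-0.55) lower and FKBP4 (0.68) higher. Their median was -0.06, or 0.05 after subtraction, and the call ended with subtraction (adjusted p = 0.0459 and 0.675). The heat shock call was also lost with an inter-gene correlation of 0.05 (adjusted p = 0.226) and among genes with a mean of at least 100 (adjusted p = 0.0507). The NRF2 and heat shock calls were also lost with ranks or log2 fold changes in place of the statistic and against random lists, and the spliceosome call with log2 fold changes and against random lists. In all, 14 of 43 lists passed, and 9 with an inter-gene correlation of 0.05.

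**Figure D3:**
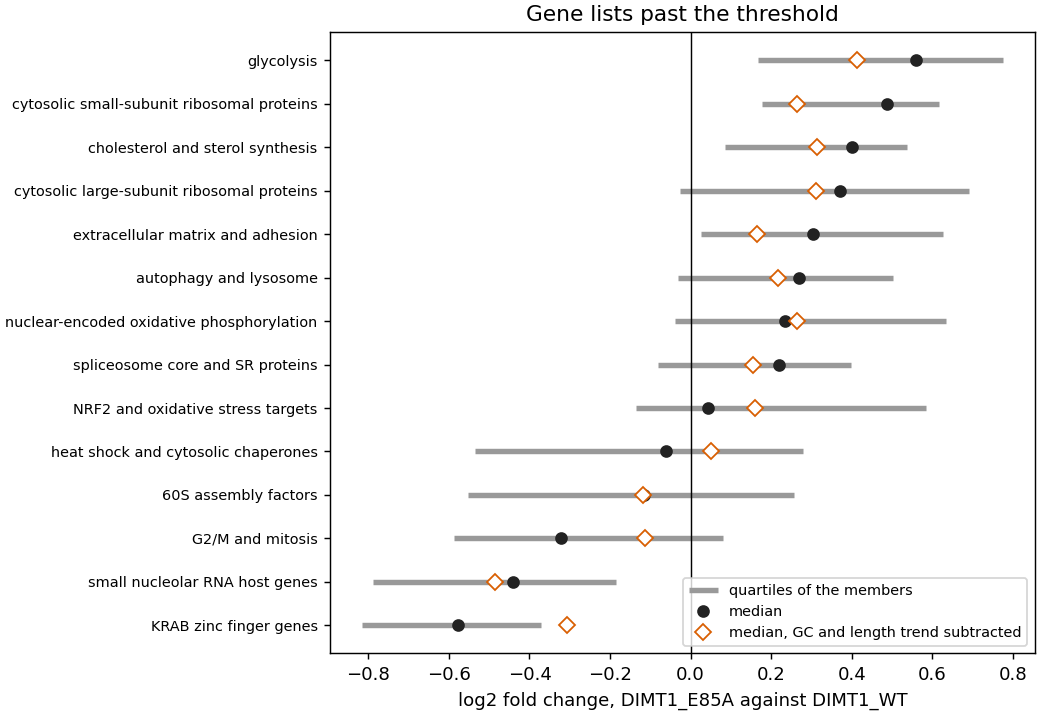
Median log2 fold change of the members of each of the 14 lists past the threshold (black points), DIMT1_E85A against DIMT1_WT, with the quartiles of the members (grey lines) and the median after the GC content and length trend was subtracted (open diamonds). Medians run from -0.58 for KRAB zinc finger genes to 0.56 for glycolysis, and the heat shock median lies at 0.05 after subtraction.

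Among the genes named in advance for ribosome assembly, the kinase genes RIOK1 (-0.63, standard error 0.0955) and RIOK2 (-0.62, 0.0932) fell in the authors' deposited table. The 18S rRNA methyltransferase gene BUD23, listed as WBSCR22, rose by 0.26 (0.0845) in the authors' deposited table. The values of NOB1 (0.20), NAT10 (0.17), EMG1 (-0.09), TSR3 (0.30), TFB1M (-0.21) and METTL5 (-0.22) did not pass in the authors' deposited table. After subtraction of the trends RIOK2 and WBSCR22 no longer passed (adjusted p = 0.0837 and 0.202). Of the stress genes, CDKN1A, a cell cycle inhibitor, rose by 0.87 (0.136), and ATF4 (-0.44, 0.0616) and DDIT3 (-0.72, 0.239) fell in the authors' deposited table, whereas MDM2 stood at 0.06 (0.0888) and did not pass. With the trends subtracted MDM2 stood at 0.36 and passed (adjusted p = 0.000438). Of the genes with the highest means, GNB2L1, which encodes the ribosomal scaffold RACK1, rose by 0.74, NPM1 fell by 0.61 and EEF1A1 stood at -0.07 (0.0645) without passing in the authors' deposited table.

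The count of changed genes depended on the null distribution. The middle of the Wald statistics was spread 2.65 times as widely as a standard normal. When this spread was taken as the null in place of the normal, 442 genes (269 higher, 173 lower) passed. Such a null holds only if the middle of the statistics comes from unchanged genes. With 40.1% of genes past the threshold, the spread can include real changes, so a count of 442 may be too low. Of the largest rises named above, only EMP3, TIMP1, GNG5 and NDUFC2 then passed. Of the largest falls, only PFDN4, CCDC181 and LARP7 did.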

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

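The tests of list medians against 0, both tests of the G2/M list and, for the small nucleolar RNAs, the tests of other RNAs without a poly(A) tail, of host reads as the whole cause, of GC content and of length were chosen only after the result was seen. For the ribosomal, glycolysis and KRAB lists a stricter bound, midway between 0 and the unadjusted median, had been fixed before the results were seen and had left 7 of 8 tests undecided; both sets of outcomes are given.

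In the authors' deposited table, 960 genes had a mean above 0 together with a log2 fold change of exactly 0 and a p of 1, so their reads lay in libraries outside the 2 compared groups. They stand out as a signal in libraries that no comparison here uses, although none of the 960 had a mean above 1.21.

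The ribosomal protein and glycolysis lists had medians above 0, and the KRAB zinc finger and G2/M lists medians below 0, along a trend with GC content. Each of these lists had members past the threshold in both directions. After the GC trend of all other genes was subtracted, the medians were 0.24 (95% bootstrap interval 0.18 to 0.46) for small-subunit and 0.31 (0.14 to 0.48) for large-subunit proteins. They were 0.42 (0.15 to 0.56) for glycolysis and -0.35 (-0.42 to -0.24) for KRAB genes. After the length trend the medians were 0.42, 0.32, 0.52 and -0.57 in the same order. All 8 intervals excluded 0 with the list test still past the threshold. Within the spread of the genes, that argues against either trend as the whole cause in these libraries. Against the bound fixed first (0.24, 0.19, 0.28 and -0.29) only length for the KRAB genes was excluded, and the other 7 tests, of GC content or length, were undecided. After the GC trend, 50.1% of the median was kept for small-subunit proteins and 84.8% for large-subunit proteins. For glycolysis 75.4% was kept and for KRAB genes 59.8%. How large a part GC content accounts for stays undecided for each list. The G2/M median moved from -0.32 to -0.10 (-0.25 to -0.03) and its call ended (adjusted p = 0.0876) because the median shrank towards 0, so that GC content and the groups cannot be told apart there, whereas after the length trend it was -0.29 and still past the threshold. The E85A variant and the amount of DIMT1 stay open and untested as biological explanations, as does a difference in library preparation between the groups, since the table holds no value per library.

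Small nucleolar RNA genes, a class looked at after 4 of them stood among the largest falls, had a median log2 fold change of -1.04 over 83 tested genes (28 lower, 1 higher, 54 not past the threshold, median mean normalized count 27.2). If host transcripts were counted on them and changed as the host gene did, each would follow its host. Yet the 43 distinct hosts, each counted once, had a median of 0.047, and 55 of 72 small RNAs lay below their host. The hosts were mixed. The 11 in the fixed list of host genes had a median of -0.63 (8 lower, 1 higher). The other 32 had a median of 0.20 (7 lower, 15 higher). Some small RNAs therefore lay in hosts that also fell. The median difference of -0.80 (95% bootstrap interval -1.07 to -0.49) excluded 0, which argues against such host reads as the whole cause. The interval crossed the bound of -0.52 fixed in advance, so how much host reads contributed stays undecided. Each host had 1 deposited value for the gene, so reads of host introns that changed otherwise were not tested. A lower yield of RNAs without a poly(A) tail would lower the class as a whole, yet 7 other such RNAs had a median of 0.61 (-0.05 to 0.84). That argues against a lower yield common to all such RNAs. The 7 are few, and only RN7SL1, RN7SL2 and RN7SK passed the threshold. The list they come from had a median length of 299 bases and 62.7% GC, so they do not test a loss of shorter RNAs alone. With the GC trend of all other genes subtracted, the median of the 74 genes with known GC content went from -1.03 to -0.96 (-1.09 to -0.76) with the list test run on this class past the threshold, which argues against GC content as the cause for the class, although SNORD27 lost its call when GC content and length were subtracted together. With the length trend subtracted it was -0.93, but only 15 other tested genes had lengths in their range, so length and loss of very short fragments cannot be told apart from a change of these RNAs, and a biological change stays open and untested.

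Genes changed in both directions across the genome, and the 2 cell populations could differ in copy number. Windows of 10 Mb explained 5.02% of the variance of log2 fold change after subtraction of the GC and length trends, against a mean of 2.78% and a highest value of 3.36% over 100 shuffles of the genes, so neighbouring genes moved together more than in any of these shuffles. The excess of 2.23 percentage points is small, which argues against copy number as the source of most of the variance left after subtraction. Regional differences that follow GC content would have been subtracted with the trend, and the variance includes measurement error. The share of changed genes that copy number accounts for was therefore not measured, and copy number differences in single regions were not excluded. Whether the E85A variant or the amount of DIMT1 produced the changes was not tested.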

How the results depend on the processing

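The subtraction of the GC and length trend, alone or with the empirical null, and the symbols as listed were chosen after the data were examined. No paired analysis was possible because the table has 1 value per gene and none per library; for the same reason the replicate block, leaving out each library, other normalizations, other count tests, pseudocounts and an estimated inter-gene correlation were not run. From 5328 changed genes, the count went to 442 with the empirical null and to 504 (379 higher, 125 lower) with the trend subtracted as well, where the wider null sets the loss, and to 313 and 2137 with a log2 fold change of at least 1 or 0.58, fewer by construction. It lay between 3614 and 6087 under the other alternatives, 3614 with the trend subtracted, of which 1552 of the higher and 1087 of the lower genes were shared with the main count and 7 were called the opposite way. The share of changed genes that were higher went from 52.4% to 48.9%, past an even split, when values were centred on the median of genes with a mean of at least 100 (0.03), to 61.7% with the trend subtracted, 75.2% with the empirical null as well and 60.9% with the empirical null alone; the cause was not tested. From 14 lists, 9 passed with an inter-gene correlation of 0.05 and 8 against random lists, where the adjusted p of the NRF2 list was 0.898 with the opposite direction; the cause was not tested. Between 11 and 16 lists passed otherwise. Of 193 named genes with GC content, 28 lost their call with the trend subtracted, and 103 of 196 lost it with the empirical null. The sign turned with the trend subtracted for TSR3 (-0.0950), TFB1M (0.0326), METTL5 (0.0915) and EEF1A1 (0.10), none past the threshold at first, and with the empirical null as well for these (-0.147, 0.0147, 0.0777 and 0.0912) and for SRF (-0.00987, from 0.35); the cause was not tested. Depth limits genes of low mean: the median standard error was 0.458 at means from 13 to 100.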

Other observations

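Lists tied to translation did not all move with the ribosomal proteins. Of 50 translation factor genes 26 rose, among them EIF3F (1.12) and EEF1G (0.79), and 14 fell, among them EIF4A2 (-0.98) and EIF3E (-0.90), in the authors' deposited table, and the list test gave an adjusted p of 0.0826, or 4.83e-05 with the GC and length trend subtracted. Of 63 genes of the small-subunit processome and 40S assembly 26 fell, among them WDR75 (-1.15) and NOP58 (-1.08), and 19 rose, among them FBL (0.91), in the authors' deposited table (adjusted p = 0.073). Proteasome genes rose in 18 and fell in 10 of 35 cases (adjusted p = 0.178, or 0.0361 with the trend subtracted) in the authors' deposited table, and fatty acid and lipid synthesis genes in 9 and 3 of 20 (0.103, or 0.0236). The fatty acid list also passed with ranks of the statistic (adjusted p = 0.0351), and the translation factor and 40S assembly lists with an inter-gene correlation of 0 (adjusted p = 0.0226 and 0.0149). Mitochondrial ribosomal proteins had 25 members higher and 14 lower of 75, RNA polymerases I and III 10 and 15 of 40, aminoacyl-tRNA synthetases 10 and 8 of 22, rRNA and tRNA modification enzymes 13 and 13 of 54, and the mRNA m6A machinery 5 and 8 of 22 in the authors' deposited table, with adjusted p of the list tests from 0.317 to 0.905. The overexpressed gene DIMT1 was among the 13 higher modification enzymes and entered the test of that list.

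Several stress and growth lists did not pass, unlike the heat shock, NRF2 and G2/M lists. In the authors' deposited table p53 targets had 6 members higher and 6 lower of 30, ATF4 and integrated stress response targets 11 and 6 of 33, the unfolded protein response 11 and 3 of 27, hypoxia targets 10 and 3 of 26, MYC targets 20 and 9 of 40, S-phase genes 13 and 20 of 50 and apoptosis regulators 7 and 6 of 30. Immediate early genes had 8 members higher and 0 lower of 30 in the authors' deposited table, with EGR1, JUND (1.39), JUN (0.76) and SRF (0.35) past the threshold and a list test short of it (adjusted p = 0.121), which passed with log2 fold changes in place of the statistic (adjusted p = 0.0155). With the GC and length trend subtracted SRF stood at 0.00196 and no longer passed (adjusted p = 0.989). Interferon (2 higher, 3 lower of 18), NF-kB (1 and 0 of 10), YAP/TAZ (3 and 2 of 21), WNT (3 and 2 of 14) and TGF-beta lists (3 and 2 of 17) did not pass in the authors' deposited table, nor did kidney (5 and 0 of 13), neuronal (3 and 0 of 21), HOX (5 and 2 of 35), histone (4 and 0 of 23), nuclear-retained RNA (2 and 3 of 10) and small RNA lists (3 and 1 of 9). Fibroblast markers had 1 higher and 0 lower of 6, and epithelial and blood markers had 2 measured members each with none past the threshold. All 13 hepatocyte markers were listed in the authors' deposited table, with 0 measured members. Of the 13 mitochondrially encoded mRNAs, 0 were listed there under the symbols used here, so their amounts are unknown.

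Standard errors were unusually wide for some abundant GC-rich genes. Of 10330 genes with a mean of at least 100, 86 had an error over 3 times that of genes with a like mean in the authors' deposited table, and 78 of the 85 with known GC content (91.8%) had at least 60% GC, against 13.8% of the other genes. FASN (0.85, standard error 0.389) and MBD3 (0.18, 0.518), named here after their values were seen, were among them in the authors' deposited table.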
